A study of Drosophila melanogaster with 2 samples.

How the data were processed

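Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, collected over 0 to 24 h, from a transgenic line that carries the zinc-finger protein D19B with green fluorescent protein (GFP) at its C terminus. Per the labels, the precipitation used an antibody against GFP and the chromatin was sonicated to 200 to 800 bp. There were 2 libraries, which the labels number as biological replicates 2 and 3, and both belonged to 1 group. The authors' peak calling used a control, and that control library is not analysed here.

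The deposited files are peak lists on 2 genome builds, dm3 and dm6. Per the file records deposited with each sample, the authors called peaks and background regions for each library and for both libraries together, and passed these lists to an irreproducible discovery rate (IDR) step that compares replicate rankings. Each of those lists held 30000 regions. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The signal value deposited for each region is the authors' own height of that peak over the control, and it is not scaled between libraries. The −log10 q of each region is likewise the authors' value, per the file format. The position of each summit was deposited as an offset from the region start, per the file format. Signal values served to describe, rank or filter regions within a list, to compare peak heights within a list, and to correlate the libraries across peaks. Read depth per library is unknown from these lists. No series column was left without a place in the design.

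All positions are 1-based dm6 coordinates. Sequence came from release 6 of the genome assembly, which shares its coordinates with dm6, and genes came from the Ensembl release 115 annotation (FlyBase 6.54). Every listed dm6 region lay within the arm lengths of that assembly. Transposable elements were left out of the genes and transcription start sites (TSSs), a choice made after the data were examined. No dm3 annotation was used, so the dm3 lists entered only counts, overlaps, correlations and arm shares. Analyses were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

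A summit was called TSS-proximal within 500 bp of an annotated TSS. Other summits were classed, in order of priority, as 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic. Class shares were tested against 10000 circular shifts of the summits within each chromosome arm, two-sided. Replicate overlap compared the 4309 regions of highest signal in each library by summits within 100 bp, with a one-sided test on the same kind of shifts. Replicate signal was compared by Spearman and Pearson correlation across peaks with 100000 permutations. Peaks per arm were tested by an exact binomial test against arm length. The heights of TSS-proximal and distal peaks were compared by a permutation test of the difference in median log2 signal, with 100000 resamples. A gene counted as occupied when a summit lay within 500 bp of one of its TSSs, and 22 gene lists were tested by two-sided Fisher's exact tests against the other protein-coding genes, or against all other genes for the RNA lists. Of the listed genes, 3 were matched under their present symbols (hry, Delta and caly) and 1 (don) was not matched; these matches were made after the data were examined. The lists also took genes by symbol prefix, as fixed beforehand.

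For sequence, 101 bp windows at summits were compared with 101 bp windows centred 500 bp away, with the side alternating between peaks. The 17 named motifs were tested by an exact sign test on paired windows, and 8-mers present in at least 20 windows by Fisher's exact test, a word and its reverse complement being 1. Benjamini-Hochberg adjustment was applied within each family of tests at 0.05. Intervals on shares are 95% exact (Clopper-Pearson) and cover counting error only. Peaks, genes and shifts are the units of all these tests, not biological replicates, and no comparison between groups of samples was possible.

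The genes named are those with the TSS nearest to each of the 15 peaks of highest signal, D19A and D19B, the 4 occupied members of highest signal of each list past the threshold and the 2 highest of each other list. This rule, the lists, the motifs and the tests were fixed before the data were examined. The binomial test of upstream against downstream summits and the comparisons of ACAGGGTA between sets of peaks or TSSs were not among those tests.

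The tests were checked on simulated data. Words planted in 200, 100 and 40 of 4309 flank windows were each recovered among 16120 words tested. The other words called were 17 that shared 5 bases with a planted word and 2 that did not. For the named motifs, 60 planted copies of 1 motif were recovered and 0 of 15 motifs that were not planted were called. Planting 200 summits at TSSs gave a call in 20 of 20 rounds, and planting none gave 0 of 20. For the gene lists, a list occupied at 4 times the rate was called in 100 of 100 rounds, against 6 of 2100 tests of the other lists. These rounds drew each gene independently at a common rate, so they do not measure false calls for lists of neighbouring genes or RNA genes. Arms drawn by length were called in 6 of 700 tests.

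Alternatives fixed beforehand were the dm3 lists, the 2154 IDR peaks of highest signal, merged neighbouring summits, other matching distances, TSS windows and flank distances, protein-coding TSSs alone, other expectations per arm, and each library's own top 4309 regions. Backgrounds of dinucleotide-shuffled windows and of the 10000 lowest-ranked regions were added after the data were examined.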

Results

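D19B-GFP occupancy was mapped in whole 0 to 24 h embryos from 2 biological replicate libraries. D19B is a zinc-finger protein, and the design asks where in the genome the tagged protein is bound. The authors' IDR list on dm6 held 4309 peaks on the arms 2L, 2R, 3L, 3R, 4 and X, with a median width of 430 bp. Together the peaks covered 1502.6 kb. Their signal ranged from 117 to 15866 with a median of 199.5, and each peak's −log10 q was at least 2.88. These 4309 peaks were exactly the regions of highest signal in the authors' list of both libraries together. In 56 cases a peak had the same region as another and a different summit. The dm3 list held 3906 peaks.

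The tallest peak lay on 2L at 480581 to 481420, with its summit at 481081 in an intron of ush, a cofactor gene of GATA factors. The nearest TSS was that of cbt, a zinc-finger transcription factor gene, 1393 bp away. Its signal was 15866 in the list of both libraries, 10240 in replicate 2 and 5652.5 in replicate 3, and it ranked 1 of 4309. The peak ranked 2 lay on X at 2137030 to 2138130, inside ph-p, a Polycomb group gene, 483 bp from an internal ph-p TSS, with a signal of 9620. The peak ranked 3 lay on 3R with its summit at 15229522, between Art3, a predicted arginine methyltransferase gene, and mRpS10, a mitochondrial ribosomal protein gene. Its signal was 6634.5, and it lay 114 bp from the Art3 TSS. Next came rdx, which encodes a BTB protein of the Hedgehog pathway, with a signal of 6582 at 326 bp from a TSS, and an intron of CG9837 with 5568.5.

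The remaining peaks among the 15 tallest had signals from 3301 to 5238. At TSSs they were those of CG43293, SLC5A11, the ankyrin gene Ank2, CG9147, CG4658 and Rgl. The others lay in introns of mub, an RNA-binding protein gene, CG4297, cu, and shn, a zinc-finger gene of the Dpp pathway. All 15 had a summit in both libraries within 100 bp, and each was higher in replicate 2 than in replicate 3.

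The gene encoding the tagged protein carried 1 of these peaks. The peak ranked 6 lay on 3L at 6184836 to 6185494, between the oppositely oriented D19B (FBgn0022699, 6182176 to 6184920, minus strand) and CG43293. Its summit at 6185104 was 184 bp upstream of the D19B TSS and 85 bp from the TSS of CG43293. The signal was 5238 in both libraries together, 3486 in replicate 2 and 1769 in replicate 3. The neighbouring zinc-finger gene D19A (FBgn0022935, 6185830 to 6189123) had a lower peak 59 bp upstream of its TSS, with a signal of 252.5 and a rank of 1579. That peak differed more between the libraries, with 216 in replicate 2 and 41.3 in replicate 3.

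**Figure D1:**
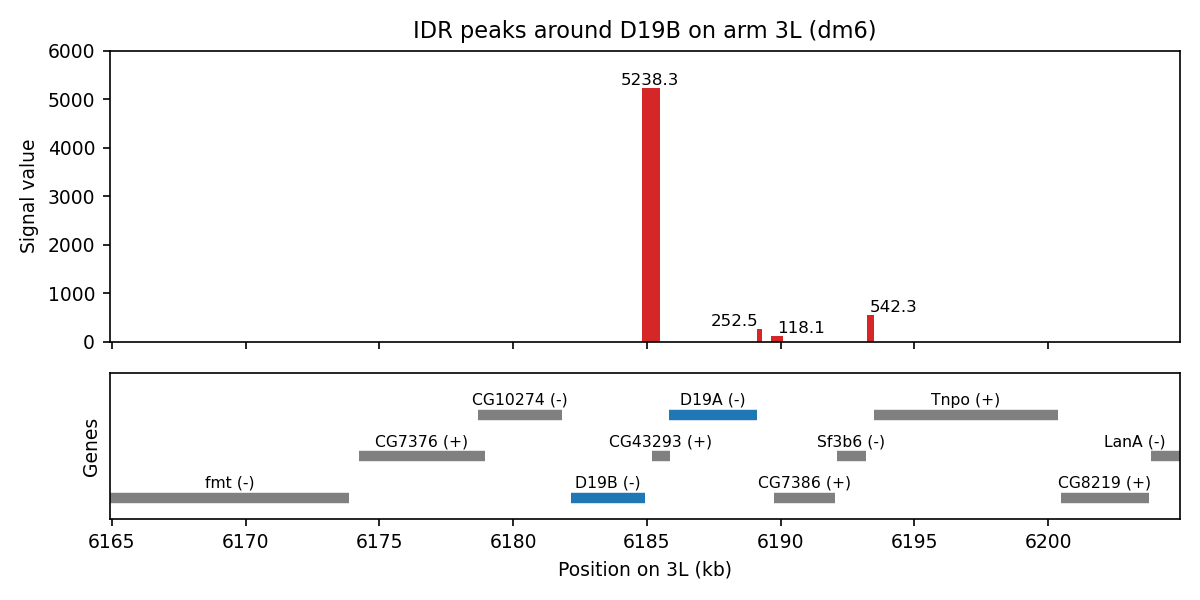
IDR peaks (red bars, width to scale, height in the authors' signal value) and annotated genes (lower panel, strand in parentheses, D19A and D19B in blue) over 20 kb on either side of the D19B TSS on 3L, in kb. The peak at D19B has a signal of 5238, and the other 3 peaks in the window have signals of 542.3, 252.5 and 118.1.

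The libraries were compared to see how far they share peaks. Of the 4309 regions of highest signal in replicate 2, 2752 (63.9%, 95% interval 62.4 to 65.3%) had a summit within 100 bp among the top 4309 of replicate 3. Shifted positions gave 0.650%, and the one-sided p was 0.0001, the smallest that 10000 shifts can give. Among all 30000 regions of the other library, 87.8% of the replicate 2 regions and 92.5% of the replicate 3 regions had a summit within 250 bp.

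Of the 4309 IDR peaks, 4164 had a summit in replicate 2, 3869 in replicate 3 and 3734 in both. Across these 3734 peaks, which are not independent replicates, Spearman's rho of the signals was 0.691 and Pearson's r of the log10 signals was 0.783, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. The value was higher in replicate 2 for 92.2% of these peaks, at a median ratio of 1.91, and the lists are not scaled to each other. At rols, a myoblast fusion gene, the peak had a signal of 924.3 in replicate 2 and no summit within 100 bp in replicate 3. Its signal in both libraries together was 1392, so the missing match does not mean that replicate 3 had no signal there.

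**Figure D2:**
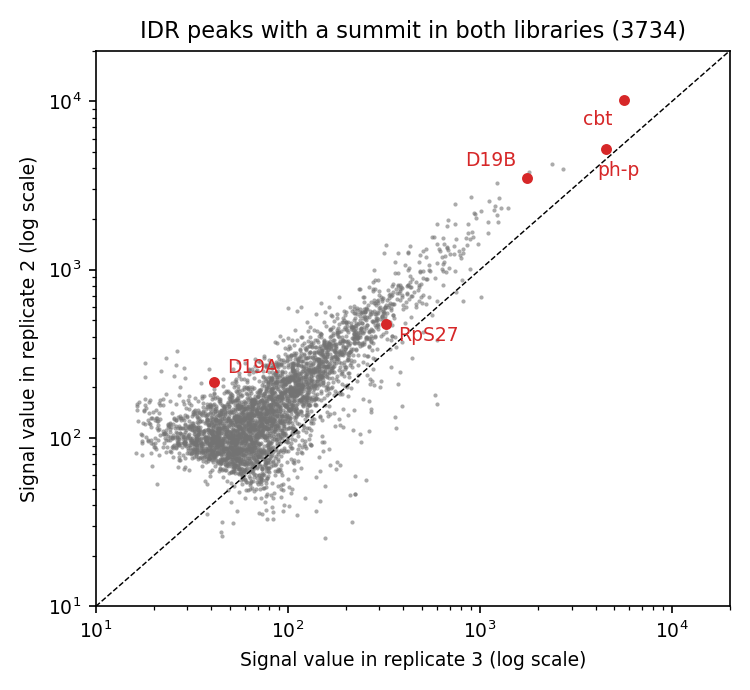
Signal value in replicate 2 against replicate 3, both on log scales, for the 3734 IDR peaks with a summit in both libraries. The dashed line marks equal values, 92.2% of the peaks lie above it, and red points mark cbt, ph-p, D19B, D19A and RpS27.

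Peak summits were concentrated at gene starts. Of the 4309 summits, 1923 (44.6%, 95% interval 43.1 to 46.1%) lay within 500 bp of an annotated TSS, against 13.6% of shifted positions, a ratio of 3.29 (permutation by circular shifts, two-sided p = 0.0002, the smallest the shifts can give). Most lay on the upstream side: 1554 TSS-proximal summits were upstream of the nearest TSS and 369 downstream (exact binomial p = 1.8e-172), with a median position of 140 bp upstream. A further 607 peaks (14.1%) lay more than 5000 bp from any TSS.

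Coding exons were the class with the lowest ratio. They held 15 summits (0.348%, and 0.603% without replicate 2), against 13.7% of shifted positions. The 3' UTRs held 1.23% against 4.45%, and intergenic sequence held 14.2% against 27.2% (permutation by circular shifts, adjusted p = 0.00035 for each of these classes). Among the lowest-ranked regions, coding exons held 4.50%, 3' UTRs 3.32% and intergenic sequence 25.25%. Part of the low coding exon share was thus common to listed regions of low rank. The coding exon ratio was 0.025 against the shifts and 0.077 against the lowest-ranked regions. Introns held 1653 summits (38.4%, against 39.5%, permutation by circular shifts, adjusted p = 0.38), and this comparison depended on the TSS window: with a window of 200 bp the intron share was 46.9%, above its shifted value of 41.5%, and with 1000 bp it was 30.3%, below 36.1% (each past the threshold). It was also lower past the threshold in the 2154 tallest peaks (35.4% against 39.5%) and against the lowest-ranked regions (48.4%). Summits in 5' UTRs and in other exons were 0.557% and 0.719% of the total and did not pass the test. The 5' UTR share passed as lower without replicate 2 (0.418% against 0.782%) and with a 1000 bp TSS window (0.116% against 0.448%).

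**Figure D3:**
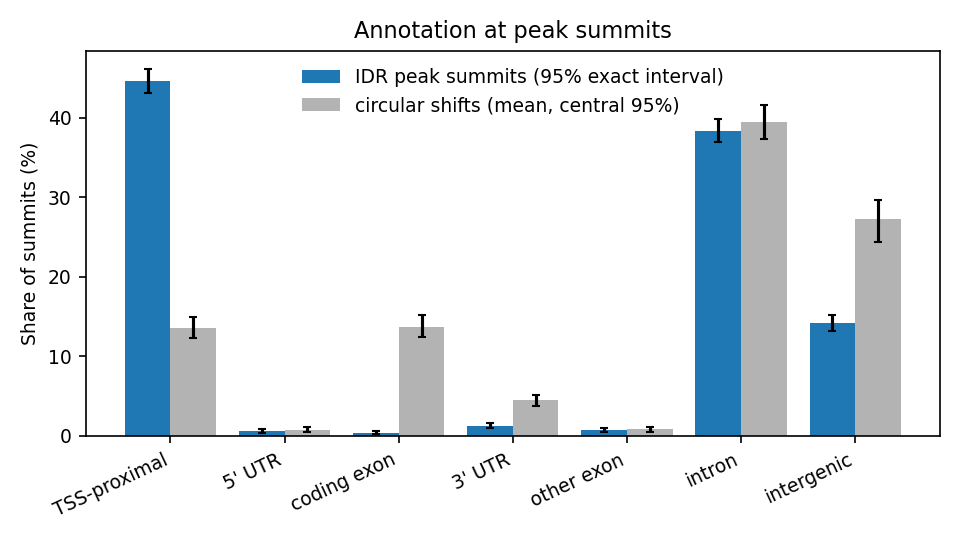
Share of the 4309 summits in each annotation class (blue, with 95% exact intervals) and in 10000 circular shifts (grey, mean and central 95% of the shifts), in percent. TSS-proximal sequence holds 44.6% of summits against 13.6% in the shifts, and coding exons hold 0.348% against 13.7%.

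Peaks at TSSs were also taller than distal peaks. Their median signal was 218.3 (quartiles 154.7 and 378.2, 1923 peaks), against 185.6 (quartiles 141.9 and 296.9) for the 2386 distal peaks. The difference of 0.23 on the log2 scale had a permutation p of 1e-05, and in single-library lists it was 0.35 for replicate 3 and 0.16 for replicate 2, each library ranked alone. The TSS-proximal share was 60.8% among the tallest 10% of peaks and 34.2% among the lowest 10%.

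Along the chromosomes, 2L and X held more peaks than their length predicts, with Y counted in the expectation. There were 843 peaks on 2L, 1.14 times the expectation (95% interval 1.08 to 1.22, exact binomial test, adjusted p = 8.1e-05), and 836 on X, 1.13 times (adjusted p = 0.00020). The dot chromosome 4, which is rich in heterochromatin, held 27 peaks, 0.639 times the expectation (0.422 to 0.929, exact binomial test, adjusted p = 0.028), and without replicate 2 this call ended (0.710, adjusted p = 0.088). No peak lay on Y. The lists of 30000 regions, background included, held 0 regions on Y for both libraries together and for replicate 3, and 1 for replicate 2, so the count of 0 and its test say nothing about occupancy there. The dm6 expectations by length and by TSS still included Y, with 114.9 peaks by length. This raised the ratios of every other arm. The arms 2R, 3L and 3R had ratios of 0.961, 0.997 and 0.959 and did not pass, but 2R passed without replicate 2 (0.925). With the number of TSSs per arm as the expectation of the exact binomial test, the 2L ratio was 1.01 (adjusted p = 0.79) and the chromosome 4 ratio 0.811 (adjusted p = 0.39), the X ratio was 1.18, and 2R passed with 0.859. On dm3, where Y did not enter, 2L and X had ratios of 1.04 and 1.05 (exact binomial test, adjusted p = 0.29 for each).

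Among 22 gene lists, the genes for cytoplasmic ribosomal proteins were the only ones occupied more often than other genes past the threshold. A summit lay at 62 of 93 of them (66.7%, 95% interval 56.1 to 76.1%), against 14.9% of other protein-coding genes (Fisher's exact test, adjusted p = 8.5e-28). These 62 genes had 66 distinct peaks. Their peaks were of moderate height: the tallest were at RpS27 (signal 799.5, rank 256), RpL7 (626), RpL34b (500.9) and RpL13A (493.2). The RpS27 summit lay 1 bp from the TSS, and the RpL7 summit 32 bp from it. In all, 2359 of 18277 annotated genes were occupied, 2133 of them protein-coding.

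Mitochondrial ribosomal protein genes were occupied at 14 of 73 (19.2%, Fisher's exact test, adjusted p = 0.55), with the tallest peaks at mRpS10 (6634.5, shared with Art3) and mRpL41 (1813). Insulator and architectural protein genes were occupied at 7 of 20 (35.0%, 95% interval 15.4 to 59.2%, Fisher's exact test, adjusted p = 0.066), including Chro (1411) and Cp190 (790.3), which encode chromatin proteins that act with insulators.

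Cuticle protein and chemoreceptor genes were occupied less often than other genes. None of 93 cuticle protein genes had a summit within 500 bp (Fisher's exact test, adjusted p = 1.6e-06, upper 95% bound 3.89%), and 1 of 179 chemoreceptor genes did (Gr39b, signal 171.4, adjusted p = 7.1e-11). Testis genes and the eggshell and yolk list did not pass. Testis genes were occupied at 1 of 25 (Mst85C, 211.3, Fisher's exact test, adjusted p = 0.40), and at 0 without replicate 2. The eggshell and yolk list gave 1 of 17 (Fisher's exact test, adjusted p = 0.58), and its occupied member was Cp190, an insulator cofactor gene that the prefix rule took in and not an eggshell gene.

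Histone genes were occupied at 3 members (2.61%, Fisher's exact test, adjusted p = 7.1e-05): His4r (319.1), His2Av (184.1) and His3.3B (151.8), each a variant or single-copy gene outside the tandem histone repeats. Without replicate 2 the share was 1.74%. Most of that list are near-identical repeated copies, at which reads are hard to place. The tRNA, snoRNA and miRNA genes were also occupied less often than other genes. Most of these other genes were protein-coding, of which 15.3% were occupied, against 5.72% of the genes annotated as ncRNA. The tRNA and snoRNA shares (5.09% and 5.86%) were near that of ncRNA genes, and the miRNA share was 2.69%. The miRNA genes named below are themselves annotated as ncRNA, so the ncRNA share is not a separate baseline for miRNA genes. By Fisher's exact test, the counts were 15 of 295 for tRNA genes (adjusted p = 4.4e-05), 16 of 273 for snoRNA genes (adjusted p = 0.00055) and 7 of 260 for miRNA genes (adjusted p = 8.4e-08). Within 200 bp of the TSS, 0 of the tRNA and miRNA genes had a summit. The snoRNA call ended in the 2154 tallest peaks (4.40% against 7.58%, Fisher's exact test, adjusted p = 0.13), and with a 1000 bp window the share was 16.5%, against 16.2% of other genes. The tallest tRNA peak had a signal of 1298 and stood for both tRNA:Asp-GTC-1-4 and tRNA:Asp-GTC-1-5, followed by tRNA:Tyr-GTA-1-8 (630.1) and tRNA:Val-CAC-2-5 (253.1). Each of these peaks also lay within 500 bp of a TSS of another gene: Sema1a, CG8036 and Naam, in this order. Of the snoRNA genes, snoRNA:Or-CD13 had a peak of 904, and 1 peak of 672.4 stood for snoRNA:Psi28S-1153 and 2 adjacent snoRNA genes. The tallest peaks at miRNA genes were those at mir-9377 (332.4), mir-34 (250), mir-2496 (220, shared with PIG-K) and mir-275 (214.9).

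The developmental lists did not pass. By Fisher's exact test, Hox genes were occupied at 0 of 8 (upper 95% bound 36.9%, adjusted p = 0.62), segmentation genes at 2 of 28 (adjusted p = 0.55; nkd, a Wingless pathway gene, 640.6, and ci, the Hedgehog pathway factor gene, 168.0) and neurogenesis genes at 3 of 36 (adjusted p = 0.55, among them elav at 871.4 and E(spl)m3-HLH at 467.0). Dorsoventral and mesoderm genes were occupied at 6 of 27 (22.2%), with htl, an FGF receptor gene, at 493.2 and dl at 448.8. Polycomb and trithorax group genes were occupied at 6 of 25, with ph-p at 9620 and brm, a chromatin remodelling ATPase gene, at 825.8.

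Among the other lists, cell cycle and replication genes were occupied at 7 of 36 (Dp 529.0, RnrS 359.2), proteasome genes at 5 of 48 (Rpn5 236.7, Rpn13 142.3), heat shock genes at 5 of 25 (Hsp27 620.8, Hsp83 509.9), muscle genes at 4 of 21 (Tm1 2291, rols 1392) and snRNA genes at 2 of 32 (snRNA:U5:35D 299.9, shared with ND-B17, and snRNA:7SKa 121.3). Among the zinc-finger genes of the ZAD list, 5 of 23 were occupied, led by D19B and pad (736.9). None of these lists passed the test, with adjusted p-values from 0.55 to 0.60. Without replicate 2 the proteasome share fell from 10.4% to 2.08% and the ZAD share from 21.7% to 13.0%, and neither passed.

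**Figure D4:**
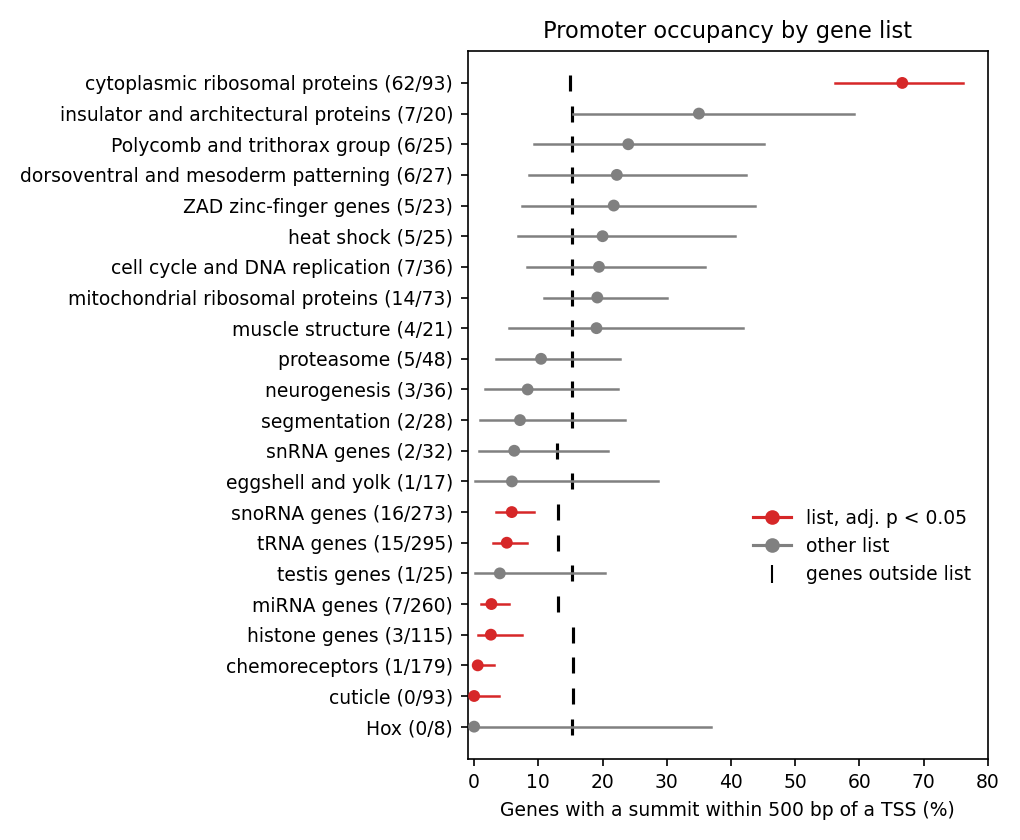
Percent of the genes of each list with a summit within 500 bp of a TSS (points) with 95% exact intervals (lines), lists with an adjusted p under 0.05 in red and others in grey, and black ticks for the genes outside the list. Cytoplasmic ribosomal protein genes stand at 66.7%, and cuticle genes at 0%.

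The sequence under the summits was searched for known words. The motif TATCGATA, bound by the insulator protein BEAF-32 and by DREF, was present in 43 of 4309 summit windows and 9 flank windows (exact sign test, adjusted p = 5.8e-06), and at TSS-proximal peaks in 33 against 4. By the same exact test, the CTCF word AGRKGGCGC was in 31 windows against 11 (adjusted p = 0.0045), the su(Hw) word TGCATACTTT in 11 against 1 (adjusted p = 0.0090) and CGATA, the core of the BEAF-32 site, in 573 against 481 (adjusted p = 0.0045). Among the 2154 tallest peaks, the ratio was 0.963 for CGATA and 1.00 for su(Hw), and the TATCGATA call ended (2.20, exact sign test, adjusted p = 0.095). The TATCGATA ratio of 4.78 fell to 2.62 without replicate 2 and 2.93 without replicate 3. The CTCF call ended with merged summits (1.94, exact sign test, adjusted p = 0.057). Without replicate 2 and without replicate 3, the su(Hw) ratios were 2.25 and 2.67 (exact sign test, adjusted p = 0.41 and 0.28), and the CGATA call ended without replicate 2 (ratio 1.09, adjusted p = 0.20). The CGATA call also ended with merged summits, with flanks 1000 bp away and against shuffled windows (ratios 1.10, 1.08 and 1.07). At distal peaks alone, only TATAAA stayed higher past the threshold.

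The TATA box word TATAAA was in 971 summit windows against 439 flanks (exact sign test, adjusted p = 8.8e-52), with 529 against 268 at distal peaks. GAGAG, the site of the GAGA factor, was in 376 against 632, GAGAGAG in 31 against 117, CACACACA in 31 against 156, GCAGCAGC in 11 against 71 (ratio 0.155, and 0.250 without replicate 2), the E-box CAGCTG in 118 against 194, the Twist site CACATG in 152 against 226 and the initiator TCAGTY in 362 against 456, each past the threshold. The TCAGTY call ended without replicate 2 (ratio 0.955), in the tallest peaks (0.851), with flanks 1000 bp away (0.874) and at distal peaks (0.837). Base composition differed between the windows: the median GC content was 32.7% at summits and 43.6% in flanks. When the summit windows themselves were shuffled with their dinucleotides kept, TATAAA was in 977 shuffled windows against 971 real ones, and none of the words listed as lower was lower past the threshold. CAGCTG (118 against 54, exact sign test, adjusted p = 5.4e-06), CACACACA (31 against 12, adjusted p = 0.0073) and GAGAGAG (31 against 14, adjusted p = 0.033) were instead higher than in shuffled windows. Both the BEAF-32 site and the CTCF word remained higher than in shuffled windows, with 43 against 7 and 31 against 8. So did the su(Hw) word, with 11 against 0 (exact sign test, adjusted p = 0.0042). The Zelda site CAGGTA was in 107 summit and 106 flank windows, and the M1BP site in 7 and 2 (exact sign test, adjusted p = 1 and 0.22). The M1BP site passed as higher in wider windows (ratio 4.75) and against shuffled windows (7 against 0), as did its core word GGTCACAC (1.75, and 18 against 4), and without replicate 2 the M1BP ratio fell from 3.50 to 1.75. AAAAAAAA was in 319 against 283 (exact sign test, adjusted p = 0.18). It passed as higher with merged summits (exact sign test, adjusted p = 0.039), without replicate 3 (ratio 1.22), in wider windows (1.16) and with flanks 1000 bp away (1.29).

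TSS-proximal peaks were also compared with 9209 TSSs of unoccupied genes. TATCGATA was present at 1.72% of occupied and 1.53% of unoccupied sites (Fisher's exact test, adjusted p = 0.58). By the same exact test, the CTCF word was present at 0.728% and 0.228% (adjusted p = 0.0037), and TATAAA was at a higher share of occupied sites, 442 of 1923 against 1453 of 9209 (adjusted p = 1.2e-12). AAAAAAAA was also higher at occupied sites (7.18% against 5.10%), and GCAGCAGC (0.260% against 1.08%), CACACACA (0.676% against 1.52%), GAGAGAG, CAGCTG and TCAGTY were lower, each past the threshold. Base composition was not matched in this comparison, and neither was position. Occupied windows were centred on summits, at a median of 140 bp upstream of the TSS, and unoccupied windows lay at the TSS itself. Words tied to a fixed distance from the TSS can differ for this reason alone.

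Without a preset list, the word with the smallest p against flanks was ACAGGGTA. It was in 128 of 4309 summit windows (2.97%, 95% interval 2.48 to 3.52%) and 2 flank windows (Fisher's exact test, adjusted p = 6.8e-32). The ratio of 64 rests on 2 flank windows, so it is sensitive to single windows. It was 22.8 without replicate 3 and 25 in the 2154 tallest peaks. The share of summit windows with the word did not fall in the tallest peaks: it was 3.48% there, against 2.46% in the 2155 other peaks. In the top 4309 regions of replicate 2 alone the share was 2.65%. Against shuffled windows ATACCCTG had a smaller p than ACAGGGTA (Fisher's exact test, adjusted p = 1.6e-30 and 1.5e-25). The overlapping words ATACCCTG (150 against 9), ACCCTGTA (113 against 2) and AGGGTATC (105 against 5) were next to it in sequence. A separate word, ATAGTCGA, was in 66 summit windows against 5 (Fisher's exact test, adjusted p = 3.1e-12). Of 13697 words tested, 1268 were higher at summits and 739 lower, and 733 of the higher ones held at most 1 G or C. Against dinucleotide-shuffled windows 187 words were higher, of which 121 were also higher than in flanks, and 42 of those 121 contained GGGTA or its complement. ACAGGGTA was more frequent at distal than at TSS-proximal peaks (98 of 2386 against 30 of 1923, Fisher's exact test, adjusted p = 2.1e-06), and it was at 6 of 9209 unoccupied TSSs.

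**Figure D5:**
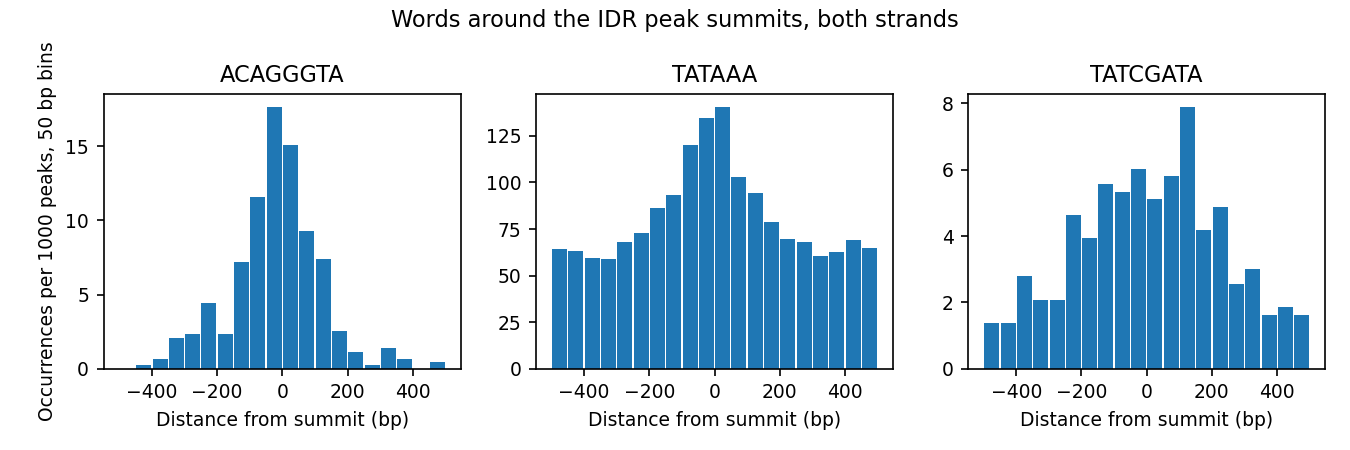
Occurrences per 1000 IDR peaks of 3 words on either strand, in 50 bp bins of distance from the summit in bp, each panel with its own vertical scale. ACAGGGTA reaches 17.6 per 1000 peaks in the bin just before the summit and TATAAA reaches 140.4 in the bin just after it, while TATCGATA is highest 100 to 150 bp after the summit, at 7.89.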

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

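The lists give no read depth, so the precision behind single peak heights is unknown. Of 73 alternative values of the main results, 61 kept their direction and threshold or stayed within 1.5 times the count, and 12 counts moved; none of the main tested values lost its call. Of 451 alternative values for single classes, arms, lists and motifs, 402 kept theirs, 24 lost a call, 15 gained one and 10 were counted as reversed. The list of both libraries together gave the IDR peaks themselves, so that alternative could change nothing. By construction, the list of the tallest IDR peaks held 2154. With protein-coding TSSs alone, 4 gene lists passed, against 7, since RNA lists could not be tested. On dm3, 1 arm passed, against 4 on dm6, of which Y carried no information and did not enter on dm3. Named motifs higher at summits numbered 5, against 2 in the tallest 2154 peaks, 8 in wider windows, 1 at distal peaks, 8 against shuffled windows, and 3 to 5 without replicate 2 or without replicate 3. Words higher at summits numbered 1268, against 696 in the tallest peaks, 1999 in wider windows, 469 at distal peaks and 187 against shuffled windows. Words lower at summits numbered 739, against 153, 2421, 139 and 46 in the same order, and 451 with flanks 1000 bp away. Fewer peaks were tested in the tallest and distal sets; the cause was not tested otherwise. Counted as reversals were the intron share with a 200 bp TSS window (46.9%), the snoRNA share with a 1000 bp window (16.5%, against 16.2% of other genes) and, in the tallest 2154 peaks, CGATA (0.963) and su(Hw) (1.00). The su(Hw) ratio of 1.00 is a loss of direction and not a change to the other side. Against shuffled windows, which have the base composition of summits, the ratio reversed for GAGAG (1.16), GAGAGAG (2.21), CAGCTG (2.19), TATAAA (0.994), CACACACA (2.58) and GCAGCAGC (2.20). Of these words, GAGAGAG, CAGCTG and CACACACA passed the threshold in the new direction. GAGAG, TATAAA and GCAGCAGC did not pass, so for them only the call was lost. The backgrounds of shuffled windows and lowest-ranked regions were chosen after seeing the data; the TSS-proximal share of the latter was 16.9%. No paired analysis was possible because there was 1 group.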

Other observations

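The gene lists, word sets and promoter classes in these paragraphs were chosen after the data were seen, as were the tests by shuffled windows and by distinct peaks per gene. Peaks lay at divergent promoters, where 2 protein-coding TSSs on opposite strands start within 500 bp of each other, more often than shifted positions did. Such promoters held 634 summits (14.7%), 6.21 times the shifted mean, and the remaining protein-coding TSSs held 1167, 2.98 times theirs (permutation by circular shifts, two-sided p = 0.0002 for each; the difference of the ratios was not tested). Of 7 further gene lists, none passed adjustment: translation factors 14 of 51 (eIF4EHP 3014, eIF5B 1226, eIF6 1210), respiratory chain 13 of 52 (ND-B17 753.7, ND-ASHI 627.9), aminoacyl-tRNA synthetases 7 of 32, small G proteins 3 of 29, cytochrome P450 10 of 85 (Cyp6a2 1267.5), serine proteases 1 of 27 and antimicrobial peptides 0 of 21. The antimicrobial list was corrected after its first result, since its symbol pattern had taken in another gene.

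Of 4 words compared, 1 differed between ribosomal protein promoters and other TSS-proximal peaks. TATCGATA was in 12 of their 66 summit windows, against 21 of 1857 other TSS-proximal windows (Fisher's exact test, adjusted p = 1.2e-09), while AGGGTAT was in 1 of 66, against 94 of 1857 (adjusted p = 0.61), and ACAGGGTA and ATAGTCGA did not differ either (adjusted p = 0.88 and 1). TATCGATA did not separate occupied from unoccupied ribosomal protein genes: it lay within 200 bp of a TSS in 18 of 62 occupied and 9 of 31 unoccupied genes, 29.0% in each (Fisher's exact test, p = 1). ACAGGGTA and ATAGTCGA were in the same window at 0 peaks, with 1.96 expected if independent (Fisher's exact test, p = 0.27). Next to ACAGGGTA, T was the base before it in 78.2% of the 124 occurrences with at least 4 bases of the window on each side, and the base after it in 67.7%.

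Some of the top 4309 regions of each library were absent from the other. Of the top 4309 regions of replicate 2, 527 had no summit within 250 bp among the 30000 regions of replicate 3, and 69.3% of these were TSS-proximal, against 44.6% of the others. Of the top regions of replicate 3, 325 were absent from replicate 2, and 28.3% of these were TSS-proximal, against 39.2%. The absent regions also had lower signal (median 102.4 against 141.2 in replicate 2 and 49.9 against 74.4 in replicate 3), and no test of these shares was run.

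The tall peak at the D19B promoter was weighed against extra copies of the locus in the transgenic line, which would raise the signal around the gene unless the authors' control carried the same copies; whether it came from the same line is not given in the sources used here. Within 20 kb of the D19B TSS there were 4 regions of the list of both libraries, against a median of 9 and a 95th percentile of 21.1 at 1000 random coding TSSs. A bound at the 95th percentile had been set to argue against extra copies, but a count inside the random spread excludes nothing, since a gain need not add regions. All 4 regions were IDR peaks, against 4309 of all 30000 listed, as raised signal would also give, so extra copies stay open. No biological explanation was tested, since the design has 1 group.

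The occupancy of ribosomal protein promoters was weighed against a general capture of highly transcribed housekeeping genes. Translation factors were occupied at 27.5% (upper 95% bound 41.7%) and respiratory chain genes at 25% (upper bound 38.9%), both below the lower bound of 56.1% for ribosomal protein genes. Counting few peaks for many genes is also argued against, with 1.06 distinct peaks per occupied gene. Transcription was not measured here, so a capture that rises only at the most active promoters stays open, and no biological explanation was tested.

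The enrichment of ACAGGGTA was weighed against base composition, transposable elements and regions of any height. The word was in 16 times as many real as dinucleotide-shuffled windows (128 against 8, Fisher's exact p = 2.5e-29). It had been picked from 13697 words in these same summit windows. The p-value and the share among IDR peaks used below are therefore not independent of that choice. Of the summits with the word, 0% lay in an annotated transposable element (upper 95% bound 2.84%), against 1.35% of all summits. Of the 10000 lowest-ranked regions, 0.380% had it (upper bound 0.521%), below the lower bound of 2.48% for IDR peaks. No biological explanation was tested.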
